A study of Oryza sativa with 6 samples.

How the data were processed

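Gene expression was measured in rice shoot apices, dissected so as to hold the shoot apical meristem and the youngest leaf primordia, in 3 wild-type (WT) samples and 3 samples of the mutant dsl1, whose affected gene encodes a histone deacetylase. Each sample was hybridised to 1 single-colour Affymetrix whole-transcript array after biotin labelling. Samples were grouped by the genotype in their titles, and replicate numbers were taken from the same titles. The labels do not say that the replicates came from separate plants or batches of plants, so p-values measure only the spread between these samples, which may be technical.

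The values used are the authors' deposited table of log2 expression, with 54922 transcript clusters (groups of probes read as 1 transcript) on each of the 6 arrays. Affymetrix Expression Console 1.3 is named in the submitters' processing notes. The background correction, normalisation and summarisation used in it are not given in the sources used here, and neither is the genome build behind the array. The deposited log2 values had array medians between 5.30 and 5.40 and were used without further scaling. Every value column belonged to 1 of the 6 samples. No 2 arrays shared the same value in more than 34 clusters, so each array was counted as a separate sample. The number of arrays limits the precision.

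Clusters were named through the platform's gene table, which lists 16269 of them: 15829 with 1 gene and 440 with several. The other 38653 clusters are unnamed here, some of which may be control probes and not transcripts, and none was named from an entry with several genes. All 15829 clusters with 1 gene matched the rice gene reference (assembly ASM3414082v1) by gene identifier. They stand for 15140 genes, of which 1740 have a common symbol and 627 have more than 1 cluster. In lists and text the cluster with the highest mean over all 6 arrays stood for a gene. The reference served only for names and for which genes neighbour each other.

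The comparison of dsl1 with WT used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, 2-sided, no block). A cluster was called at a Benjamini-Hochberg adjusted p under 0.05 over all 54922 clusters, with no fold minimum. Gene lists were tested with camera from the same package at a preset inter-gene correlation of 0.01, adjusted over the lists tested, on 1 cluster per gene and with at least 5 measured members. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera takes its p from the few degrees of freedom that 6 arrays leave. It thus passes fewer lists even at the same correlation. Camera asks whether a list shifted more than other genes, and fry whether it shifted at all. Neighbouring genes called in the same direction were counted along the chromosomes and set against 10000 permutations of the calls, one-sided. Median changes were taken in 5 equal groups of clusters, numbered from 1 (dimmest) to 5 (brightest) by their mean over all 6 arrays.

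The tests, alternatives, naming rule and 37 gene lists were fixed before the data were examined. Those lists searched symbols and descriptions, and the reference held symbols for few genes: 5 lists reached 5 measured members, 10 had fewer and 22 had none. Another 46 lists matched on gene symbols were written after the annotation was seen and before any comparison was computed, and 43 of them reached 5 members. The naming rule took up to 12 called genes with a name in each direction, and where fewer than 5 were called, the 5 with the smallest unadjusted p in that direction, given as values that did not pass. It also took every histone deacetylase and, from each list, up to 4 called members or at most 1 other as a value. Genes named outside this rule are said to have been chosen after their values were seen.

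The fit was tested on simulated data with the means of the real clusters and their spread as moderated by limma. Noise was drawn independently for each cluster, and 200 clusters were changed by 1 to 4 on the log2 scale. For dsl1 against WT over 54922 clusters, it called 42% of those changed by 1 on the log2 scale and 96% of those changed by 2, with 15 false calls and no called cluster in the wrong direction. On the 15829 gene-paired clusters alone it called 71.4% of those changed by 1. The share called depends on how many clusters change and by how much, so these shares do not give the power in the real data. The list test, run on 15140 simulated genes and 43 lists, called the 1 list that had been shifted by 1 and also 1 list that had not.

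Alternatives were quantile normalisation again, median centring, leaving out the dimmest 33.3% of clusters, fitting only clusters with 1 gene, a variance trend, a robust prior, array weights, the replicate number as a block, leaving out each array in turn, a minimum log2 fold change of 1, and the 2 other list tests. Leaving out the rows listed before the first gene-paired cluster, and counting repeated rows once, were added after the data were seen, as was following the adjusted p of single lists, fixed ones included, and the medians by expression group through the alternatives. Figures were drawn with matplotlib 3.10.9.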

Results

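Transcript levels were measured in shoot apices of rice plants at the emergence of a young leaf, in 3 WT samples and 3 samples of dsl1, a dwarf mutant with slender leaves and a lesion in a histone deacetylase gene. Histone deacetylases remove acetyl groups from histone tails and are generally associated with repression of transcription. The comparison asks which transcripts differ in the apex, which holds the meristem and the first leaf primordia, when this enzyme is altered. Each array gave a log2 level for 54922 transcript clusters. The correlation between arrays was 0.9704 to 0.9795 within WT, 0.9796 to 0.9806 within dsl1 and 0.962 to 0.978 between genotypes. Some WT pairs were thus no closer than some pairs across genotypes. WT replicate 3 had a mean correlation of 0.9752 with the other WT arrays and 0.9759 with the dsl1 arrays. On the first principal component, which held 32.3% of the variance, the 3 WT arrays lay at -67.8 to -9.97 and the 3 dsl1 arrays at 25.9 to 59.1, with WT replicate 2 farthest out.

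The differences with the smallest p lay in genes and transcripts without a common name. Only 1809 of the 54922 clusters carry such a name, so this says little about which kinds of genes differ. Among gene-paired clusters, LOC9270481 rose in dsl1 by 4.40 on the log2 scale, from 5.43 ± 0.566 to 9.84 ± 0.291 (SD, n = 3 each), a 21.1-fold difference with a limma adjusted p of 0.0192. LOC4342415 rose by 2.88 (SE 0.183, adjusted p = 0.0192). LOC4326256, LOC4324554 and LOC4346846 rose by 1.59, 1.53 and 1.40, with adjusted p of 0.0396, 0.0392 and 0.0416. LOC4350616 fell by 3.12 on the log2 scale, from 7.60 ± 0.539 to 4.48 ± 0.174 (SD, n = 3 each, adjusted p = 0.0416). These 6 genes were outside the naming rule, since they carry no common symbol, and were chosen after their values were seen.

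In all, 8 clusters rose and 6 fell in limma at an adjusted p under 0.05, and in each of the 14 the 3 dsl1 values lay wholly above or below the 3 WT values. The other 8 of the 14 were not paired with a gene. Without the 7793 rows listed before the first gene-paired cluster, which are noisier and often repeated and may be control probes, 36 rose and 16 fell, a setting added after the data were seen. The deepest fall, cluster 15953597, went from 7.05 ± 0.114 to 2.79 ± 0.361 (SD, n = 3 each), a log2 change of -4.26 with a limma adjusted p of 0.00757. Its dsl1 level is close to the mean of the dimmest of 5 equal groups of clusters, 2.81, so the size of this fall is uncertain. At an unadjusted p under 0.05, 3328 clusters were higher and 3131 lower, 11.8% of all. Groups did not overlap in 19.4% of clusters, against the 10% that chance gives for 3 against 3. The counts rested on every array: without WT replicate 3 or without dsl1 replicate 1 no cluster passed, with 6033 and 4908 clusters at an unadjusted p under 0.05, while without WT replicate 1, WT replicate 2, dsl1 replicate 2 and dsl1 replicate 3 the higher counts were 1, 3, 0 and 4 and the lower counts 0, 2, 1 and 4. Of these calls 1, 4, 1 and 2 were among the 14.

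Of the 1740 genes with a common symbol, none passed in limma over all clusters, while 200 were higher and 71 lower at an unadjusted p under 0.05. The 5 with the smallest p on the higher side follow. LEA19, a late embryogenesis abundant protein of the drought response, was at 2.10 ± 0.323 in WT and 4.63 ± 0.431 in dsl1 (SD, n = 3 each, limma adjusted p = 0.078). Its WT level is under the mean of the dimmest of 5 equal groups of clusters, 2.81, so the size of this difference is uncertain. OsPP2C59, a protein phosphatase of the PP2C family, was 5.32-fold higher (adjusted p = 0.0801), and JAMYB, a jasmonate-inducible MYB transcription factor, 5.08-fold higher (adjusted p = 0.11). NAC45, a NAC transcription factor, differed by 1.81 ± 0.194 (SE) on the log2 scale and MGD2, a galactolipid synthase, by 1.26 ± 0.133, with adjusted p of 0.082 and 0.0801.

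On the lower side, BGLU5, a beta-glucosidase, stood at 6.11 ± 0.116 in WT and 4.54 ± 0.314 in dsl1 (SD, n = 3 each, limma adjusted p = 0.092). MADS18, a MADS-box gene of the floral transition, differed by -0.73 (SE 0.123, adjusted p = 0.193). LFL1, a B3-domain gene linked to the repression of flowering, differed by -0.68, OsSWEET3a, a sugar transporter, by -0.87, and DNG701, a DNA glycosylase that removes methylated cytosine, by -0.73, with limma adjusted p of 0.238, 0.238 and 0.24. The dsl1 levels of LFL1 and OsSWEET3a were low, at 2.93 and 2.34. None of these 10 differences passed the test. HDA703, listed as HDAC3, was the only histone deacetylase matched by symbol, and its levels were 2.66 ± 0.162 in WT and 2.64 ± 0.222 in dsl1 (SD, n = 3 each, adjusted p = 0.97), with a difference whose sign turned to 0.041 on quantile normalisation. Both levels of HDA703 are close to the mean of the dimmest of 5 equal groups of clusters, 2.81, so the lack of a difference says little. Whether HDA703 is the gene altered in dsl1 is not given in the sources used here, and no value of the mutated gene is reported.

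**Figure D1:**
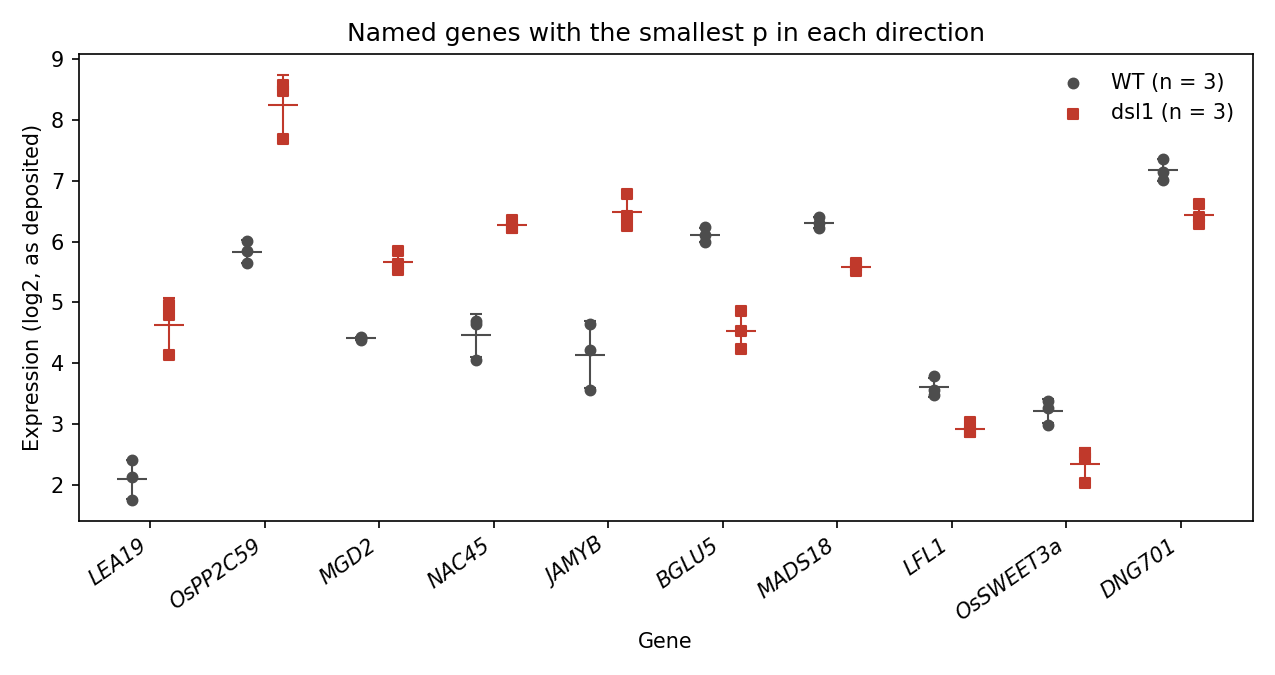
Deposited log2 expression (y axis) of the 10 named genes with the smallest p in either direction (x axis), with 1 point per array, horizontal bars for group means and error bars for the SD. The 3 dsl1 values of LEA19 lie between 4.14 and 4.96 and its 3 WT values between 1.76 and 2.40, and none of the 10 differences passed an adjusted p of 0.05 over all clusters.

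When only the 15829 clusters with exactly 1 gene entered the fit, 59 rose and 16 fell, among them 17 genes with a common symbol, 16 higher and 1 lower. The 1 lower gene was BGLU5. The higher ones not yet given were chosen after their values were seen. ASMT1, a methyltransferase of melatonin synthesis, was 14.7-fold higher and salT, a salt-induced lectin listed as ML, 14.1-fold higher, with adjusted p of 0.0453 and 0.0396 in this fit and 0.176 and 0.162 over all clusters. LIS, a linalool synthase, was 4.14-fold higher (adjusted p = 0.0432 in this fit and 0.165 over all clusters). Of the regulators, NAC077 differed by 1.61, IAA6, an auxin-response repressor, by 1.25, and G1L2, of the ALOG family of leaf and spikelet genes, by 1.11 on the log2 scale. The WT level of NAC077 was low, at 2.89, so the size of its difference is uncertain. S1PL, a sphingolipid lyase, HAK5, a potassium transporter, GST-II, a glutathione transferase, and CYP707A6, which breaks down abscisic acid, differed by 0.83 to 0.99 or, for CYP707A6, by 0.76. CH16, a chitinase, was 6.61-fold higher (adjusted p = 0.0251 in this fit and 0.124 over all clusters). Over the 14 alternatives ASMT1, salT, LIS and CH16 passed in 1 each, this fit, and their adjusted p reached 0.498, 0.49, 0.498 and 0.372.

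Among the lists fixed in advance, the seed storage protein list fell as a set: camera gave an adjusted p of 0.0203, with a median log2 change of -0.30 over 5 genes. This call was lost with an estimated correlation (adjusted p = 0.188). All 5 members were lower, 2 of them at an unadjusted p under 0.05, and none passed, whether adjusted over all clusters or adjusted over the list alone. Members named here and for the lists that follow were chosen after their values were seen. The glutelin gene GluB5 differed by -0.42 and GLUA1 by -0.40. MSRA5, a methionine sulfoxide reductase matched through its symbol only and no storage protein, differed by -0.30. Without MSRA5 the list holds fewer than 5 measured members and would not have been tested. The call of this list therefore rests on a false match. Without WT replicate 2 the adjusted p of the list was 0.119. The symbol list of seed storage genes, which leaves out MSRA5 and adds GLUB2, GLB and RA14, did not pass: of its 7 genes 6 were lower and 1 higher, with a median of -0.22 and a camera adjusted p of 0.275 (0.817 with an estimated correlation).

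The remaining 4 fixed lists did not pass. The jasmonate list had a median of 0.42 over 8 genes and a camera adjusted p of 0.0523 (adjusted p = 0.188 with an estimated correlation). Over its alternatives the adjusted p lay on both sides of the threshold, from 0.00473 without WT replicate 3 to 0.188 with an estimated correlation. It was 0.0416 on median centring and 0.0747 on quantile normalisation, and 0.138 and 0.119 without WT replicates 1 and 2. Its JAZ members, repressors of jasmonate signalling, were on the higher side, with JAZ4 at 0.56 and JAZ6 at 0.98. The list also holds GATA17, GATA18 and GATA20, zinc-finger factors that share a TIFY motif and are no jasmonate repressors, at -0.013, 0.19 and -0.088. The wider symbol list of 20 jasmonate genes, without the GATA genes, had a median of 0.25 and a camera adjusted p of 0.275 (0.897 with an estimated correlation, and 0.00194 without WT replicate 3), with OPR7, of an enzyme family that includes jasmonate synthesis, at -0.54. The 16 cyclins and B-type cyclin-dependent kinases had a median of 0.13 (adjusted p = 0.131), with 3 at an unadjusted p under 0.05 and CYCD5-3 at 0.53. The 5 YABBY genes had a median of -0.083 (adjusted p = 0.42), and the 5 diterpenoid phytoalexin genes one of 0.11 (adjusted p = 0.929). In these 4 lists no member passed when adjusted over all clusters, and none when adjusted over the list alone.

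Among the symbol lists, the chitinase family, mostly enzymes that break down fungal cell walls, rose as a set, with a median of 0.98 over 8 genes and a camera adjusted p of 0.000605. With an estimated correlation the call was lost (adjusted p = 0.468), while fry, which asks whether a set changed at all and not whether it changed more than other genes, gave 0.032 after adjustment. The estimate, -0.037, was below the preset 0.01, so correlation between the members does not account for the loss. The loss comes with the fewer degrees of freedom of that form of the test. Its unadjusted camera p was 0.0109, against 1.41e-05 at the preset. Of the 8, 6 were higher at an unadjusted p under 0.05 and 4 passed when adjusted over the list alone, but none passed over all clusters. Among the 6 was Chib3H-a, also listed as XIP-I, a xylanase inhibitor of this family, at low levels of 1.89 in WT and 2.21 in dsl1. CH16 (Cht1) went from 4.83 ± 0.336 to 7.55 ± 0.673 (SD, n = 3 each, limma adjusted p = 0.124), CH6 was 4.53-fold higher and Cht2 3.83-fold higher, while Chia1d differed by -0.020.

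The NAC transcription factor list rose as a set, with a median of 0.36 over 7 genes and a camera adjusted p of 0.0191 (adjusted p = 0.575 with an estimated correlation, and 0.032 with fry). Here too the estimated correlation, -0.041, was below the preset, so the loss again comes with the fewer degrees of freedom. NAC45, NAC077 and NAC6 differed by 1.81, 1.61 and 0.91, passing when adjusted over the list alone and not over all clusters, and NAC010 by -0.29. Without WT replicate 1 the adjusted p of the list was 0.0686, and without the dimmest 33.3% of clusters 0.0654. The other 41 symbol lists had camera adjusted p between 0.105 and 0.967.

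Lists of genes from other tissues, states and families were among those that did not pass. The photosynthesis list, taken as markers of greening leaf, had a median of -0.18 over 20 genes (camera adjusted p = 0.105, and 0.896 with an estimated correlation), with 17 lower and 3 higher, of which 1 in each direction had an unadjusted p under 0.05. This list also holds chlorophyll synthesis genes such as CHLH and PORB, and GLN2 and Fd-GOGAT of nitrogen assimilation. Over its alternatives the adjusted p lay on both sides of the threshold. It was 0.0447 on quantile normalisation, and 0.0133, 0.0238 and 0.0371 without WT replicate 3, dsl1 replicate 1 and dsl1 replicate 3. With 1 array left out it reached 0.455, without dsl1 replicate 2. The highest values were 0.568 with fry and 0.896 with an estimated correlation. Casparian strip-like genes, a family active in many organs and so no marker of root, had a median of 0.092 over 14, and laccases of lignifying tissue one of -0.12 over 10, with adjusted p of 0.324 and 0.4. Epidermal genes had a median of 0.14 over 6 (adjusted p = 0.309), MADS-box genes 0.0025 over 21 (adjusted p = 0.894) and heat shock genes 0.12 over 24 (adjusted p = 0.306). When adjusted over the list alone, 2 MADS-box genes passed as higher and 1 as lower. In the casparian strip-like, epidermal and heat shock lists 1 gene each passed as higher and 0 as lower.

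**Figure D2:**
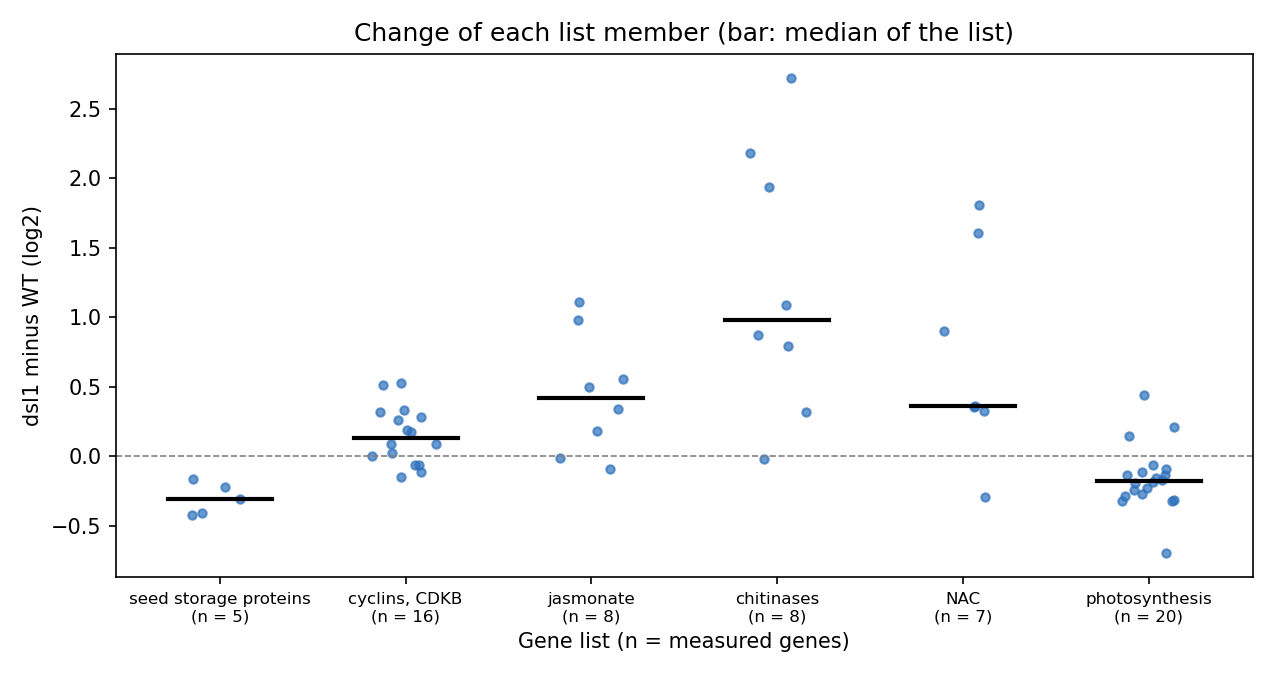
Log2 difference between dsl1 and WT (y axis) for each measured gene of 6 lists (x axis), with 1 point per gene and a bar for the median. The chitinase median is 0.98 and the photosynthesis median -0.18.

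The symbol list of KNOX homeobox genes, of which OSH1, OSH15 and OSH71 belong to the class tied to meristem identity and the others do not, did not pass, with a median of 0.22 over 7 genes (camera adjusted p = 0.275, and 0.817 with an estimated correlation). Of these 7, 6 were higher and 1 lower, 3 of the higher ones at an unadjusted p under 0.05, and none passed when adjusted over the list alone. OSH71 differed by 0.57, OSH15 by 0.35, OSH1 by 0.15 and OSH45 by -0.29. Lists with fewer than 5 measured genes were described and not tested, among them the WOX homeobox genes, which differed by -0.28 (WOX4) to 0.20 (WOX6).

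Along the chromosomes, no neighbouring pair among 15139 genes was called in the same direction in limma, with 6 genes called and a permuted mean of 0.0015. At an unadjusted p under 0.05, a threshold that was not among the tests fixed in advance, there were 203 such pairs among 2268 genes. Permutations gave 182 (p = 0.0491, one-sided permutation test). The largest excess of such genes on any chromosome, 24.8, lay within what permutation gave (p = 0.26). The 73 genes called in the fit of gene-paired clusters held 1 pair (p = 0.206, one-sided permutation test). With only 6 genes called over all clusters, their spread over chromosomes says little (p = 0.821, one-sided permutation test).

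Weakly expressed clusters were slightly lower in dsl1, while the most strongly expressed group lay near 0, at -0.0052 to 0.0607 with 1 array left out. The median log2 change was -0.071 in group 1, the dimmest of 5 equal groups by mean level, -0.066 in group 2, -0.045 in group 3, 0.015 in group 4 and 0.031 in group 5, the brightest. Of the 14 calls, none lay in the dimmest group, where 300 clusters were higher and 596 lower at an unadjusted p under 0.05 in limma, and 1 lay in the brightest, where 1029 were higher and 532 lower. After quantile normalisation the median was -0.022 in the dimmest group and 0.00542 in the brightest, and turned to -0.020 in group 4.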

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

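Over the 54 genes and unnamed clusters followed, 625 alternative values kept side and direction, 90 lost and 18 gained the threshold, and 5 changed sign. All 90 losses were of the 14 called clusters, the only followed ones that had passed. These passed in 5 of 12 alternatives (cluster 15953555) to 9 of 13 (cluster 15953597), so the calls were not stable. Outside these 14, a value that kept its side stayed without passing. All 5 changes of sign were of HDA703, whose difference was 0.041 on quantile normalisation and -0.148 to 0.061 with 1 array left out. The others were taken for their small p in these same arrays, so their directions were likely to hold. The variance trend, robust prior, block and fit of clusters with 1 gene leave each log2 difference as it is by construction. The handling of repeated and early unnamed rows, and all alternatives for the symbol lists, for the adjusted p of any single list, fixed ones included, and for the medians by expression group, were chosen after the data were seen. Leaving out 1 array left 0 to 4 clusters higher and 0 to 4 lower, with fewer samples in each fit. Fitting only clusters with 1 gene gave 59 higher, 16 lower and 1 adjacent pair, with fewer clusters tested. Leaving out the rows before the first gene-paired cluster gave 36, 16 and 1. Those 7793 rows hold 3459 distinct sets of values, with a median residual SD of 0.458 against 0.195 for gene-paired clusters. Counting repeated rows once gave 17 higher. All 14 calls remained in both of those fits. Leaving out the dimmest 33.3% gave 12 higher and 5 lower, and a variance trend 12 and 6.

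Same-numbered arrays did not deviate together (correlations -0.064, -0.125 and -0.052), which gives no sign that the numbers mark pairs. With the replicate number as a block, 1 cluster was higher, 0 were lower (5220 at an unadjusted p under 0.05) and 2 fixed lists passed, the jasmonate list at 0.0276. That 1 cluster was not among the 14, so all 14 calls were lost. The block leaves the log2 differences as they are but takes up degrees of freedom, so this loss is no sign of pairing. By deviation from the group means no array was closest to the array of its own number, but by level WT replicate 3 and dsl1 replicate 3 were closest to each other across genotypes (0.978).

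The count of fixed lists was 2 on median centring and with a variance trend, 0 without the dimmest clusters, where the seed storage and chitinase lists had fewer than 5 members, 0 with an estimated correlation, 0 with fry, 0 with a median of at least 1, and 0 to 3 with 1 array left out. The count of symbol lists was 0 without the dimmest clusters, 0 with an estimated correlation and 0 with a median of at least 1, and 2 to 4 with 1 array left out. Seed storage adjusted p was 0.188 with an estimated correlation, 0.0723 with fry and 0.00798 to 0.119 with 1 array left out. The chitinase value was 0.468 and the NAC value 0.575 with an estimated correlation, and NAC was 0.0654 without the dimmest clusters and 0.00472 to 0.0686 with 1 array left out. A robust prior does not enter camera, so it was not run for lists, and the fit of clusters with 1 gene leaves lists as they are by construction.

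The medians by expression group were -0.0223, -0.0339 and -0.0195 in groups 1, 2 and 4 on quantile normalisation, and -0.0034, 0.0428 and 0.0781 in groups 3, 4 and 5 on the fit of clusters with 1 gene. Group 4 ran from -0.0152 to 0.0284 and group 5 from -0.0052 to 0.0607 with 1 array left out, both negative without WT replicate 2. The cause of these changes was not tested where the text names none.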

Other observations

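Of the tests below, the random placement of calls, the clusters of the run that kept their level, and the photosynthesis and jasmonate medians were chosen only after the result was seen. Other gene groups did not pass as lists. In the potassium transporter list, 5 of 21 genes were higher and none lower at an unadjusted p under 0.05 in limma, with HAK5 at 0.98, HAK15 at 0.56 and a list median of 0.10 (camera adjusted p = 0.275), and 2 passed when adjusted over the list alone. In the cytokinin list, 4 of 26 were higher and none lower, with a median of 0.26 (adjusted p = 0.275). In the list of heading date and clock genes, 4 of 16 were lower and none higher, with a median of -0.24 (adjusted p = 0.275). No member of the cytokinin or the heading date list passed when adjusted over the list alone.

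With 10 splits of the 6 arrays into 3 and 3, the share of splits is never under 0.05. The real split gave 8 clusters higher and 6 lower, and the highest count in 1 direction among the others was 0, so that 1 of 10 splits gave as many of either. At an unadjusted p under 0.05 limma gave 6459 clusters in the real split and 1412 to 3160 in the others. The other splits mix the genotypes on each side, so any genotype difference widens their spread and lowers their counts of clusters. In the fit of gene-paired clusters it gave 75 calls, again in 1 of 10 splits, and the others at most 0. For fixed lists the real count was 1, the highest other was 1, and 3 of 10 splits gave as many. For symbol lists the real count was 2 and 6 of 10 splits gave as many, with 7 in the split that set WT replicates 1 and 2 and dsl1 replicate 3 against the rest. A structure of the arrays other than genotype and a preset correlation that calls lists too freely were not told apart by a test. With an estimated correlation 0 symbol lists passed, but that form has so few degrees of freedom that this does not decide the question. For the 2 lists of the real split, chitinases and NAC, the estimate lay below the preset, so correlation between members does not account for the loss of their calls. Adjacent pairs numbered 0 in all 10 splits.

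A run of lower clusters lies in the order of cluster numbers on chromosome 4, between the genes LOC4335005 and LOC4335022, and holds 3 of the 6 clusters that fell in limma, at -2.05, -2.25 and -4.26, among 29 clusters, 5 of them at an unadjusted p under 0.01. In 10000 random placements of the calls, a share of 2e-04 held as many calls of 1 direction within 50 clusters, but the window was set once the run was seen and neighbouring clusters may measure 1 transcript, so scatter by chance stays open. Of the 9 clusters of the run expressed above the median level in WT, 5 had a 95% interval of the log2 change above -1, and 3 of 6 at a higher cut, with the brightest at 10.42 in WT and 10.22 in dsl1, which argues against loss of the whole stretch unless these probes bind other sequences. This rule was written after the values were seen, in place of one on clusters not called, which had excluded it but left out the called ones, and one on the lower quartile, which had left it open. A stretch of sequence that differs between the plants may still account for it: 0 of 12 clusters on the opposite strand were changed at p under 0.01, but the median random stretch also holds 0, so the bound set in advance was too weak, and at the rate of the run so few would be seen with a probability of 0.103, a condition added after the value was seen.

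The higher chitinases did not rest on 1 array, since their lowest median with 1 array left out was 0.831. A larger share of expanded leaf in dsl1 would raise photosynthesis genes, whose median was -0.085 at its highest with 1 array left out. Against it stand 17 of 20 of these genes lower and camera adjusted p of 0.0133 to 0.0447 in 4 alternatives, but these genes move together (estimated correlation 0.486) and fry gave an unadjusted p of 0.336, so the direction is not set beyond its spread and this stays open, a condition added after the value was seen. Wounding or handling at dissection could raise them too: the jasmonate median was at least 0.254 with 1 array left out, and since handling and genotype cannot be told apart here, it too stays open, beside an effect of the mutation, which was not tested.

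The tilt from lower dim clusters to brighter ones, 0.102 between the medians of the dimmest and the brightest of 5 groups, was 0.0277 after quantile normalisation. Since that step gives all arrays 1 distribution and shrinks such a tilt whatever its source, this does not decide whether the deposited arrays differed in distribution for a technical reason. As for variation between arrays unrelated to genotype, 0 of the other splits gave a tilt as large, the highest being 0.0772, and 10 splits are too few to decide.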
